A study of Mus musculus with 12 samples.

How the data were processed

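RNA from mouse peritoneal macrophages was measured on 12 one-colour Agilent oligonucleotide arrays, 3 in each of 4 groups: C57BL/6 control, C57BL/6 with apoA-I, MyD88-null control and MyD88-null with apoA-I. Groups and replicate numbers were taken from the sample titles and source names. The free-text descriptions disagreed with these for C57BL/6 control replicate 2, whose description includes the apoA-I step, and for MyD88-null apoA-I replicate 2, whose description leaves it out. The titles and source names were followed in the results, and both ways of resolving the conflict were run as alternatives.

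The scanner files hold spot intensities made with Agilent Feature Extraction, version 9.5 per the submitters' processing notes and versions 9.5.1.1 and 9.5.3.1 per the file headers. Per the file headers, the processed intensity of a spot is its Cy3 signal after background correction and detrending within the array. Processed intensities were not scaled between arrays: their 75th percentiles ran from 199.5 on MyD88-null apoA-I replicate 1 to 1408 on C57BL/6 control replicate 3. The mean spot intensity and the local background intensity in the same deposited files are raw pixel summaries. A deposited table of processed values for the same arrays holds values that follow the log10 processed intensity of each array, with correlations across spots of 0.99257 to 0.99974. The log10 scale of that deposited table was read from this match. Its normalization is not given in the sources used here, and the centring of its columns stays unknown. The medians of its columns for replicates 1, 2 and 3 were 1.8435, 1.8408 and 1.8283 in C57BL/6 controls, and 1.8402, 1.841 and 1.8346 in C57BL/6 cells with apoA-I. They were 1.8386, 1.8676 and 1.8435 in MyD88-null controls, and 1.8333, 1.846 and 1.8225 in MyD88-null cells with apoA-I. That table served only as an alternative.

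Each array carried 45018 spots, of which 43379 were not controls. These belonged to 41174 probes, and the spots of the 245 probes printed more than once were averaged. From the deposited intensities, log2 values were computed as log2 of the processed intensity minus the array's 75th percentile of it. Spots marked as outliers by Feature Extraction were left out and saturated spots were kept; no array had more than 6 saturated probes. A probe was kept if it was well above background on all arrays of at least 1 group, which left 24351 probes. For each gene the probe with the highest mean was used, which gave 16744 genes. Results for every probe on its own were computed as an alternative. Where a named gene had several probes they moved in the same direction in each comparison it passed, but at least 1 further probe did not pass for Lpar6 and Dusp4 in MyD88-null cells, Marcksl1 in C57BL/6 cells, Pde4b in C57BL/6 cells and between control cells, and Peli1 and Rnd1 in both genotypes.

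Probes were named through a table of mouse RefSeq genes of assembly GRCm38.p6, used for names only. By this table, 22951 probes were named through their accession, 121 through another RefSeq accession, 6582 by a current symbol and 3078 by a unique synonym, while 8442 kept the name in the file. Coordinates are those of the array files, which give build mm7 and place 40442 probes. They mark the position of the probe, and exon annotation of that build was not used here.

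Genes were compared with limma 3.58.1 in R 4.3.3 (with the packages jsonlite 2.0.0 and data.table, version 1.17.8). A single linear model with a mean for each of the 4 groups was fitted to all 12 arrays, so that all comparisons shared an estimate of the spread, with 8 residual and 2.16 prior degrees of freedom. The comparisons were apoA-I against control in each genotype, the difference of these responses (the interaction), and MyD88-null against C57BL/6 in control and in treated cells. P-values were two-sided and adjusted over all genes by the Benjamini-Hochberg method, with a threshold of 0.05. SE denotes the standard error of a log2 change and SD the standard deviation over arrays. Beside the median of a gene list, SE comes from the spread over its members. Members are not independent replicates, so that SE does not measure the spread between samples.

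A probe not well above background on any array of a group has only a bound there, and where it was above background on only some arrays of a group their number is given. For such genes the fold is given as at least a number: the mean of the brighter group against the mean, per array, of the higher of the probe's own value and the lowest value among probes well above background. Medians of gene lists were also computed with such genes at their bound.

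The rule for naming genes was fixed before the data were examined, as were the gene lists, the tests and most alternatives. It took, among genes past the threshold whose groups did not overlap, the 12 with the largest increase and the 10 with the largest decrease in each response to apoA-I, in the interaction and between genotypes in control cells. Where fewer than 5 genes passed, it took the 5 with the smallest p in each direction, and it added up to 4 members of each list and Myd88. Probe IDs, accessions, clones, RIKEN symbols and predicted genes were counted but left out of the naming.

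The 27 lists fixed in this way were NF-kappaB pathway genes, cytokines, chemokines, immediate early genes, interferon-stimulated genes, inflammatory effector genes, negative regulators of cytokine signalling, TLR signalling components, cholesterol synthesis and SREBP2 targets, LXR targets and cholesterol efflux genes, lipid uptake and storage genes, unfolded protein and integrated stress response genes, NRF2, metal and heat shock genes, hypoxia and glycolysis genes, cell cycle genes, alternative activation genes, and markers of macrophages, resident large peritoneal macrophages, B cells, T cells, NK cells, neutrophils, eosinophils, mast cells, dendritic cells, mesothelial cells and fibroblasts, and red blood cells. List shifts were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, with adjustment over the 130 tests of each method. P-values of lists are those at the preset correlation unless marked otherwise. Members were also tested with adjustment over the list alone. The single measured red blood cell marker was not tested as a list.

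The sample titles number the 3 replicates of each group and do not say whether a number marks 1 experiment. Samples of the same number deviated together from their group means, with correlations of 0.296 to 0.859 in the 12 pairs, so the 4 samples of a number were treated as paired and are called an experiment here. The fit with the experiment as a replicate block is therefore given beside results whose call or count it changed. The arrays lay on 5 slides and were scanned on 3 days. Day 3 held the 4 samples numbered 3 and no others. Their 75th percentiles of 603.7 to 1408 lay above those of all other arrays, at 199.5 to 591. A difference between scan days or in brightness can also make same-numbered samples deviate together, so the correlations do not establish pairing. Other alternatives were normexp background correction with an offset of 50, quantile normalization, the deposited processed values, no filter or a stricter filter on dim probes, each probe on its own, the slide as a fixed or random block, a trended and robust variance, array weights, only the arrays compared, a minimum change of 2-fold, each array left out in turn, and other windows around Myd88. The scan day as a block, the 2 arrays of slide 2 left out, the slide block for the list tests and a hold-out that selects genes in 8 arrays were added after the data were seen.

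The test was run on simulated data for 16728 genes, with 200 genes changed, in 5 simulations. For the response in C57BL/6 cells it found 15.5%, 54.6% and 87.6% of genes changed by a log2 value of 1, 2 and 4, and 4.73% of its calls were false. For the difference of the responses it found 1.49%, 33.7% and 74.5% of genes at the same sizes. In a contrast with no change it called 0 genes. The simulated noise was independent between genes and arrays, with no difference between experiments, slides or brightness. The real samples of a number deviated together, so these rates hold for the simulated setting only.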

Results

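Gene expression was measured in peritoneal macrophages, phagocytes drawn into the abdominal cavity of mice by an irritant, thioglycollate. The cells came from female mice aged 10 weeks, either C57BL/6 or lacking MyD88, the adaptor protein through which most Toll-like receptors and the interleukin-1 receptor signal. They were collected 96 h after the injection and loaded overnight with cholesterol at 10 µg/ml. They then stood in medium with polymyxin B, an antibiotic that binds bacterial lipopolysaccharide, at 25 µg/ml. ApoA-I, the main protein of high-density lipoprotein and an acceptor of cellular cholesterol, was added to some of the wells at 10 µg/ml for 2 h. From each sample, 500 ng of total RNA was labelled with Cy3 and hybridised to a one-colour array. The series title asks which transcripts apoA-I induces and how far that depends on MyD88.

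Each of the 4 groups held 3 arrays, numbered as replicates 1 to 3. The 4 samples of a number deviated together from their group means and are called an experiment here, although the labels do not say that a number marks one. Samples numbered 3, and no others, were scanned on day 3, so a difference between scan days can also make them deviate together. Between 57.56% and 73.64% of the 41174 probes were well above background on an array. Replicate arrays of a group correlated at 0.915 to 0.979 across genes, which are not independent replicates. Nothing in the labels says which animals or pools gave which sample, so p-values measure the spread between these samples, which may be technical. The small number of arrays limits the precision of every value. The descriptions of C57BL/6 control replicate 2 and MyD88-null apoA-I replicate 2 name the opposite treatment to their titles and source names, and the titles and source names were followed.

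The single Myd88 probe (mm7 chromosome 9, 119016408 to 119016467) was well above background on all 12 arrays. Its mean log2 signal relative to the array's 75th percentile was 3.31 ± 0.303 (SD, n = 3) in C57BL/6 controls and 3.96 ± 0.481 (SD, n = 3) with apoA-I. In MyD88-null cells it was 1.79 ± 0.358 (SD, n = 3) in controls and 2.81 ± 0.415 (SD, n = 3) with apoA-I. The log2 level was lower by a difference of -1.33 (SE 0.227, 2.52-fold) in MyD88-null cells, with limma's adjusted p = 0.0532, or 0.000939 with the experiment as a block. The null samples lay lower in each of the 3 experiments under both treatments, with differences of -1.61, -1.39 and -1.56 in controls and -1.42, -1.04 and -0.98 with apoA-I. The lower level in every pair goes with the genotype labels but does not by itself establish them. The probe may lie outside the deleted part of the gene, so the signal left in null cells does not count against the labels.

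The first comparison asked which transcripts apoA-I changed in C57BL/6 macrophages. ApoA-I raised a broad set of inflammatory genes within 2 h. Il1b, which encodes interleukin-1 beta (chromosome 2, 129105464 to 129105523), showed the largest increase among the named genes, a log2 change of 8.75 (SE 0.326, n = 3 per group), or 430-fold, with adjusted p = 1.52e-06. Il6, a fever-inducing cytokine (chromosome 5, 29052734 to 29052793), rose by 8.26 (SE 0.416, adjusted p = 7.68e-06), a 308-fold change from a control level that was above background on 1 of 3 arrays. Il12b, the p40 subunit of interleukins 12 and 23 (chromosome 11, 44370372 to 44370431), rose at least 69.6-fold (adjusted p = 5.04e-06), and Edn1, the precursor of the vasoconstrictor endothelin-1, at least 64.4-fold (adjusted p = 4.71e-06). Here and in what follows, "at least" marks a gene not well above background on any array of its dimmer group.

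In all, 139 of 16744 genes passed in C57BL/6 cells, 136 higher and 3 lower with apoA-I, and 1242 genes had an unadjusted p under 0.05. The other named increases were Csf2 (at least 34.4-fold) and Il23a (at least 24-fold), which encode cytokines of myeloid and T cell responses, Ptgs2 (81.2-fold), the inducible cyclooxygenase, the chemokine Ccl4 (60.9-fold), Il1a (52.8-fold), the costimulatory ligand Tnfsf9 (48.8-fold), the neutrophil attractant Cxcl2 (57.5-fold) and the small GTPase Rnd1 (39.9-fold). The other probes of Rnd1 gave log2 changes of 1.73 and 2.03, with adjusted p of 0.509 and 0.141 among probes. The 3 genes that fell were the zinc finger genes Zfp239, by a log2 change of -1.10 (SE 0.189, adjusted p = 0.0278), and Zfp78 (at least 2.07-fold, adjusted p = 0.0475), and the peroxisomal gene Pex10, by -0.96 (SE 0.184, adjusted p = 0.0475). Their calls were lost in 8, 10 and 10 of the 12 fits with an array left out, with adjusted p of up to 0.153, 0.209 and 0.284. The call of Cxcl2 was lost in 4 of these fits, with adjusted p of up to 0.0805. The 3 arrays of each group did not overlap for any of the 139 genes, which chance gives for 10% of genes and which held for 13.1% of all genes.

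Gene lists fixed in advance gave the same picture by group. All 19 measured cytokines of 20 had positive changes with apoA-I, with a median log2 change of 4.0 that was the same with the 4 members known only as a bound set at that bound. Of these, 11 rose over all genes and 15 when adjusted over the list alone, and none fell (camera adjusted p = 4.14e-42). Among 16 measured chemokines of 18, 9 rose over all genes and 12 adjusted over the list alone, led by Ccl4 and Cxcl2, with a median of 2.63 (adjusted p = 4.84e-27). Among 21 inflammatory effector genes of 22, 8 rose and 19 adjusted over the list alone, with a median of 2.59 (adjusted p = 2.2e-37). They included Ptgs2, the costimulatory receptor Cd40 at 3.86 (SE 0.4), Acod1, the enzyme that makes itaconate, at 3.53 (SE 0.489), and the arginine transporter Slc7a2 at 3.33 (SE 0.398).

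Of the 17 NF-kappaB pathway genes, which encode the transcription factor's subunits, inhibitors and direct targets, 8 rose over all genes and 16 adjusted over the list alone (median 1.62, adjusted p = 3.63e-32). Examples were the inhibitor family member Nfkbiz at 3.99 (SE 0.399), the adhesion molecule Icam1 at 3.09 (SE 0.274) and the deubiquitinase Tnfaip3 at 2.72 (SE 0.331). Of 23 interferon-stimulated genes, 8 rose and 14 adjusted over the list alone (median 1.54, adjusted p = 4.77e-22), among them the ubiquitin-like modifier Isg15 at 4.46 (SE 0.485) and the antiviral GTPase Mx2 at 3.54 (SE 0.425). Of 10 negative regulators of cytokine signalling, 4 rose and 7 adjusted over the list alone (median 1.32, adjusted p = 1.31e-14), led by Cish at 4.47 (SE 0.526) and Socs3 at 3.37 (SE 0.331). Of 23 measured immediate early genes of 24, 2 rose over all genes, Maff at 3.15 (SE 0.209) and Ier3 at 1.97 (SE 0.376). Adjusted over the list alone, 8 rose and 1 fell, the AP-1 subunit Jun at -1.74 (median 0.89, adjusted p = 1.88e-10). The immediate early list's call was lost with an estimated correlation (adjusted p = 0.0546 with an estimated correlation), while the others kept theirs at far larger p-values. Camera's adjusted p with an estimated correlation was 0.0017 for cytokines and for chemokines and 0.00449 for inflammatory effectors. It was 0.00465 for NF-kappaB genes, 0.0254 for interferon-stimulated genes and 0.00449 for negative regulators. The call of Ier3 was lost in 9 of the 12 fits with an array left out, with adjusted p of up to 0.258.

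Few genes of lipid handling passed. None of the 24 cholesterol synthesis genes passed (median 0.15, adjusted p = 0.107), and none of the 15 LXR targets and efflux genes did over all genes (median -0.042, adjusted p = 0.458). Abca1, the transporter that passes cholesterol to apoA-I, changed by 0.24 (SE 0.262, adjusted p = 1). Abcg1, a transporter that passes cholesterol to high-density lipoprotein, fell when adjusted over the list alone, and over all genes its change was -1.10 (SE 0.216, adjusted p = 0.0544, or 0.00798 with the experiment as a block). Of 14 lipid uptake genes, the oxidised lipoprotein receptor Olr1 alone rose, at 3.0 (SE 0.578, adjusted p = 0.0475), a call lost in 9 of the 12 fits with an array left out (adjusted p of up to 0.232). The list's median was -0.034 and its mean 0.17 (adjusted p = 0.872). The NRF2, metal and heat shock list (14 of 15 measured, median 0.31, adjusted p = 0.00294), the unfolded protein and integrated stress list (16 measured, median 0.24, adjusted p = 0.000831) and the hypoxia and glycolysis list (12 measured, median 0.27, adjusted p = 0.0126) shifted up with the preset correlation only (adjusted p = 0.284, 0.202 and 0.0761 with an estimated correlation). The last pair of these calls were also lost without C57BL/6 apoA-I replicate 3 (adjusted p = 0.0553 for each). Medians moved to 0.18 for the NRF2 list and 0.46 for the unfolded protein list without C57BL/6 control replicate 3, to 0.41 for the latter without C57BL/6 apoA-I replicate 1, and to 0.41 and 0.17 for the hypoxia list without C57BL/6 control replicate 2 and C57BL/6 apoA-I replicate 3. Over all genes they held 0, 1 and 1 risen members, the glutathione-degrading enzyme Chac1 at 1.44 (SE 0.244; lost in 6 of the 12 fits, with adjusted p of up to 0.113 without C57BL/6 control replicate 1) and the peptide hormone Adm at 2.99 (SE 0.326). The 19 TLR signalling components held no changed gene over all genes and 1 risen gene adjusted over the list alone (median 0.22, adjusted p = 0.0375, 0.174 with an estimated correlation, 0.113 with the experiment as a block and up to 0.112 without C57BL/6 control replicate 2). That call was also lost without C57BL/6 apoA-I replicate 1 (median 0.10, adjusted p = 0.11) and MyD88-null control replicate 1 (adjusted p = 0.0514). Its median was 0.089 without C57BL/6 control replicate 3.

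No marker list of a cell type passed with apoA-I in C57BL/6 cells. Medians were -0.30 for 7 macrophage markers, 0.001 for 5 resident peritoneal macrophage markers, -0.060 for 7 B cell, 0.23 for 7 T cell, 0.13 for 2 NK cell, 0.028 for 7 neutrophil, -0.16 for 3 eosinophil, 0.24 for 6 mast cell, 0.13 for 3 dendritic cell and 0.19 for 11 mesothelial and fibroblast markers, with adjusted p from 0.276 to 0.879. The single red blood cell marker changed by -0.044. F10, coagulation factor X, was the 1 marker that rose, at 1.69 (SE 0.244, adjusted p = 0.00907), a call lost in 2 of the 12 fits with an array left out (adjusted p of up to 0.0679, without C57BL/6 apoA-I replicate 2). Neither the 7 measured alternative activation genes (median 0.0065, adjusted p = 0.384) nor the 21 cell cycle genes (median 0.049, adjusted p = 0.808) passed as a list, although Mki67, a marker of proliferating cells, rose at 2.79 (SE 0.305, adjusted p = 0.00147) and no other cell cycle gene passed.

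With the experiment as a block, 570 genes passed in C57BL/6 cells, 396 higher and 174 lower, so that the share of higher calls was 69.5% instead of 97.8%, and all 139 genes were among them. Within slides 1 and 3, which held both groups, cytokine medians were 3.68 and 4.22 and NF-kappaB medians 1.53 and 2.01, and within scan days 1 and 3 they were 4.37 and 3.8 and 1.71 and 1.54. The count was 69 and 83 without C57BL/6 control replicates 2 and 3, 92 and 66 without C57BL/6 apoA-I replicates 1 and 2, and 59 without both samples whose descriptions conflict. With the treatment taken from those descriptions, limma called 0 genes, with 306 at an unadjusted p under 0.05. Those descriptions make both C57BL/6 samples of experiment 2 treated. Yet these samples differed by medians of 4.22 for cytokines and 2.01 for NF-kappaB genes. Experiments 1 and 3 gave 3.68 and 3.8 for cytokines and 1.53 and 1.54 for NF-kappaB genes. These values argue against the description of C57BL/6 control replicate 2.

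**Figure D1:**
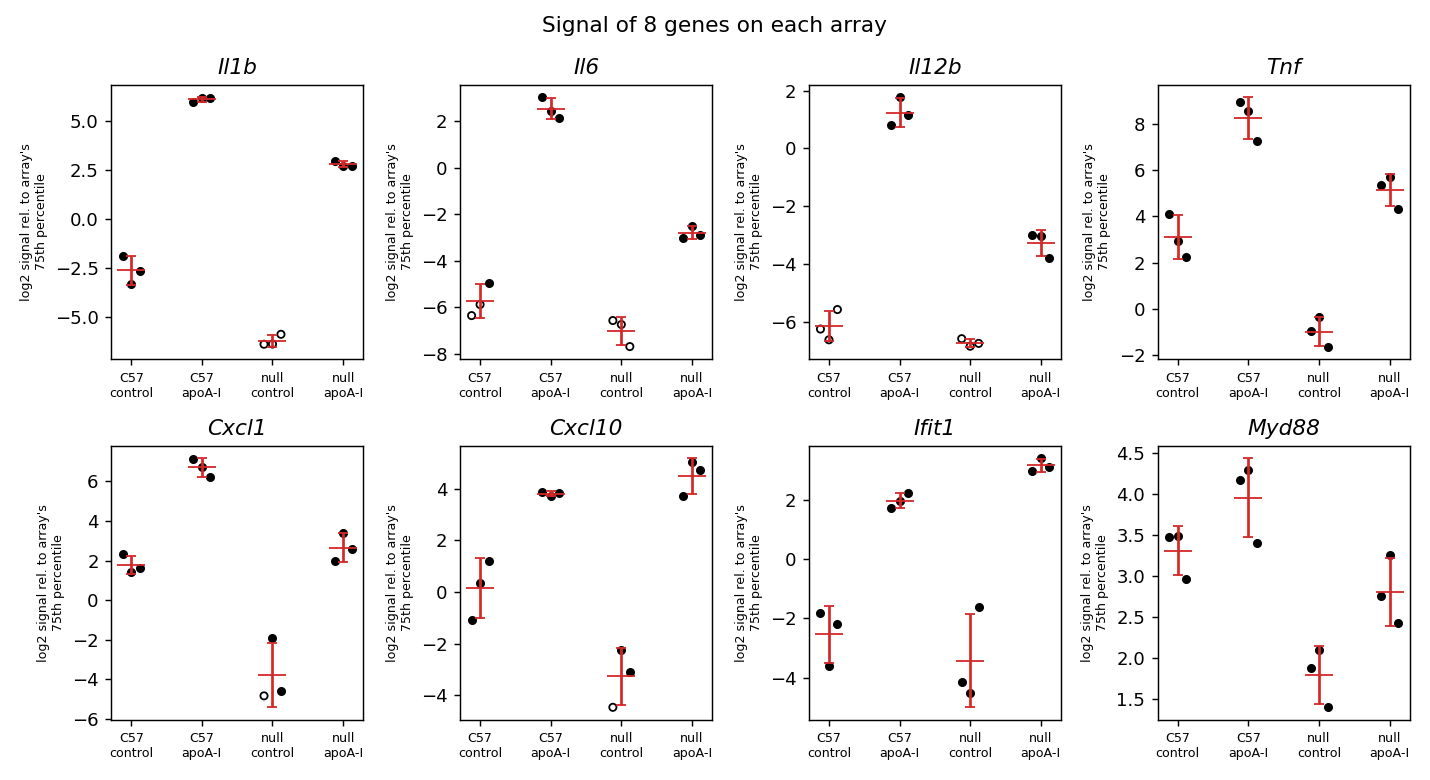
Signal of 8 genes on each of the 12 arrays, as log2 relative to the array's 75th percentile, with a red mean and SD per group; open circles are arrays on which the probe was not well above background. Il1b rose from -2.64 to 6.11 with apoA-I in C57BL/6 cells and from -6.24 to 2.79 in MyD88-null cells, where no control array was well above background.

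The same question was asked of macrophages without MyD88. ApoA-I raised inflammatory genes there too. Il1b rose at least 212-fold (adjusted p = 1.1e-06, n = 3 per group), and Cxcl10, an interferon-induced chemokine (chromosome 5, 92334002 to 92334061), rose by a log2 change of 7.76 (SE 0.653), or 217-fold, with adjusted p = 0.000218, from controls above background on 2 of 3 arrays. Ifnb1, interferon beta (chromosome 4, 87925845 to 87925904), rose at least 48.1-fold (adjusted p = 0.00126). Acod1 rose by 7.12 (SE 0.489), 139-fold, with adjusted p = 8.21e-05, and Tnf, tumour necrosis factor (chromosome 17, 33296067 to 33296126), by 6.13 (SE 0.603), 69.8-fold, with adjusted p = 0.000534.

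In MyD88-null cells 191 genes passed, 189 higher and 2 lower, with 1451 at an unadjusted p under 0.05. The other named increases were Cxcl2 (at least 111-fold), the interferon-induced Ifit1 (95.8-fold), Rnd1 (95.4-fold, with log2 changes of 2.54 and 3.45 and adjusted p of 0.146 and 0.00652 at its other probes), Cxcl1 (86.7-fold, from controls above background on 2 of 3 arrays), Tnfsf9 (83.7-fold), Olr1 (51.5-fold) and the guanylate-binding protein Gbp5 (48.4-fold). Lpar6, a receptor for lysophosphatidic acid, fell by a log2 change of -2.09 (SE 0.369, adjusted p = 0.0221), a call lost in 5 of the 12 fits with an array left out, with adjusted p of up to 0.108. The other gene that fell, A530053G22Rik at -3.41 (SE 0.467, adjusted p = 0.00456), lies outside the naming rule and was chosen after its values were seen. The groups did not overlap for any of the 191 genes, which chance gives for 10% of genes and which held for 11.6% of all genes.

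By list, 11 of 16 chemokines rose in MyD88-null cells over all genes and 15 adjusted over the list alone (median 3.79, adjusted p = 7.58e-28). Of 23 interferon-stimulated genes, 12 rose and 19 adjusted over the list alone (median 2.86, adjusted p = 6.82e-28), led by Ifit1, Mx2 at 5.26 (SE 0.425), Isg15 at 4.77 (SE 0.485) and Oasl1 at 3.85 (SE 0.555). Of 17 NF-kappaB pathway genes, 13 rose and 16 adjusted over the list alone (median 2.41, adjusted p = 1.06e-34), with the inhibitors Nfkbia at 4.78 (SE 0.384) and Nfkbie at 4.65 (SE 0.367) first. Of 21 inflammatory effectors, 12 rose and 15 adjusted over the list alone (median 2.86, adjusted p = 1.94e-28), among them Acod1, the actin-regulating Marcksl1 at 4.99 (SE 0.488) and Ch25h, the enzyme that makes 25-hydroxycholesterol, at 4.57 (SE 0.56). Of 19 cytokines, 10 rose and 13 adjusted over the list alone (median 3.11, adjusted p = 3.14e-24). With the 7 cytokines known only as a bound set at that bound, the median was 1.72. Of 10 negative regulators, 4 rose and 5 adjusted over the list alone (median 1.22, adjusted p = 2.26e-08), including Socs3 at 3.4 (SE 0.331) and the ubiquitin ligase Peli1 at 2.47 (SE 0.268). These 6 lists kept their calls with an estimated correlation (camera adjusted p = 0.0017, 0.0145, 0.00449, 0.00671, 0.00449 and 0.0161, in the order given). The immediate early list (2 risen over all genes, Maff and Dusp4, and 12 risen and 2 fallen adjusted over the list alone, median 1.46, adjusted p = 2.3e-08) did not, with adjusted p = 0.0829 with an estimated correlation. The call of Dusp4 was lost in 3 of the 12 fits with an array left out (adjusted p of up to 0.0718, without MyD88-null apoA-I replicate 1).

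The lipid lists again held few changed genes in MyD88-null cells: 0 of 24 cholesterol synthesis genes (median 0.034, adjusted p = 0.436), 0 of 15 LXR targets (median -0.052, adjusted p = 0.591) and, of 14 lipid uptake genes (median -0.080, adjusted p = 0.666), Olr1 alone. Abca1 changed by 0.83 (SE 0.262, adjusted p = 0.295). TLR components had a median of 0.20 (adjusted p = 0.57), and the unfolded protein list (median 0.29, adjusted p = 0.114, with Chac1 risen), the NRF2 list (median 0.080, adjusted p = 0.233) and the cell cycle list (median 0.0051, adjusted p = 0.823, with Mki67 risen at 3.34, SE 0.305) did not pass. The call of Chac1 was lost in 3 of the 12 fits (adjusted p of up to 0.0674, without MyD88-null apoA-I replicate 2). Resident peritoneal macrophage markers shifted up with the preset correlation (median 0.52, adjusted p = 0.0456), but not with an estimated correlation (adjusted p = 0.152 with an estimated correlation), with the experiment as a block (adjusted p = 0.12) or without MyD88-null control replicate 1 (median 0.30, adjusted p = 0.33). The call was also lost without C57BL/6 apoA-I replicate 3 (adjusted p = 0.0537) and MyD88-null apoA-I replicates 2 and 3 (0.0592 and 0.191). Without MyD88-null control replicate 2 the median was 0.89. F10 alone of them rose over all genes, at 1.43 (SE 0.244), a call lost in 4 of the 12 fits (adjusted p of up to 0.103, without MyD88-null control replicate 1). The other marker lists did not pass: medians were -0.13 for macrophages, 0.050 for B cells, 0.58 for T cells, 0.59 for NK cells, 0.14 for neutrophils, 0.15 for eosinophils, 0.15 for mast cells, 0.63 for dendritic cells and 0.30 for mesothelial cells and fibroblasts.

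In MyD88-null cells 682 genes passed with the experiment as a block, 580 higher and 102 lower, so that 85% of calls were higher instead of 99%, and all 191 genes were among them. Within slides 2 and 4, interferon-stimulated medians were 3.21 and 2.09 and chemokine medians 3.27 and 3.6, and within scan days 1, 2 and 3 they were 3.56, 3.21 and 2.09 and 5.2, 3.27 and 3.6. The count was 126 without MyD88-null control replicate 1, 115 without MyD88-null apoA-I replicate 2, 102 without the 2 arrays of slide 2 and 90 without both samples whose descriptions conflict. With the treatment taken from those descriptions it was 0, with 760 genes at an unadjusted p under 0.05. Those descriptions leave both MyD88-null samples of experiment 2 untreated. Yet these samples differed by medians of 2.65 for NF-kappaB and 3.48 for interferon-stimulated genes. Experiments 1 and 3 gave 2.49 and 2.37 for the former and 2.32 and 2.09 for the latter. These values argue against the description of MyD88-null apoA-I replicate 2.

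Responses in both genotypes were then set side by side. Of the 136 genes higher with apoA-I in C57BL/6 cells, 113 were also higher in MyD88-null cells, against 1.535 for independent lists. With the experiment as a block, the overlap was 274 higher genes, against 13.72 for independent lists, and 47 lower genes, against 1.06. All 136 had a positive change in MyD88-null cells, and 188 of the 189 genes higher in those cells had a positive change in C57BL/6 cells. The responses correlated across genes with Pearson's r = 0.5057 and Spearman's rho = 0.4062, where genes are not independent replicates. Over the 136 genes the median log2 change was 2.59 (SD 0.296 over 3 experiments) in C57BL/6 cells and 2.73 (SD 0.311) in MyD88-null cells. With genes known only as a bound set at that bound, 11 in C57BL/6 and 15 in MyD88-null cells, the medians were 2.56 and 2.51. The rise was larger in C57BL/6 cells for 62 of the 136, a set chosen on its C57BL/6 values, which favours that genotype.

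**Figure D2:**
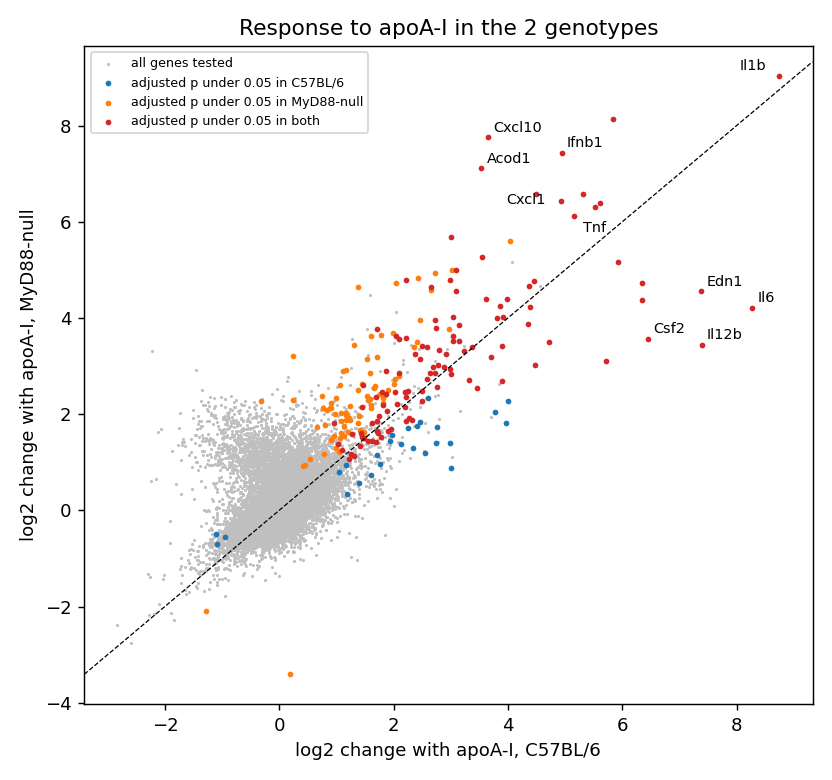
Log2 change with apoA-I in MyD88-null cells (vertical) against C57BL/6 cells (horizontal) for each of 16744 genes, coloured by where the adjusted p was under 0.05; the dashed line marks equal changes. Il6, Il12b, Csf2 and Edn1 lie below the line and Cxcl10, Acod1 and Ifnb1 above it, while no gene passed the test of the difference.

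The interaction asked whether the response itself differed between genotypes. With limma, 0 of 16744 genes passed, 196 had an unadjusted p under 0.05, and the smallest adjusted p was 0.17. With the experiment as a block the count was also 0, with 1232 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0819. The genes with the smallest p, named although they did not pass, had smaller estimated increases in MyD88-null cells for Il12b at -3.94 (SE 0.49, adjusted p = 0.17), Il6 at -4.05 (SE 0.589, adjusted p = 0.326), Edn1 at -2.82 (SE 0.467, adjusted p = 0.326), Il1a at -2.61 (SE 0.467, adjusted p = 0.481) and Csf2 at -2.89 (SE 0.622, adjusted p = 1). Estimated increases were larger for Acod1 at 3.59 (SE 0.692, adjusted p = 0.652), Nfkbie at 3.26 (SE 0.519, adjusted p = 0.326), the chemokine Cxcl11 at 2.96 (SE 0.482, adjusted p = 0.326), the phosphodiesterase Pde4b at 1.98 (SE 0.407, adjusted p = 0.953) and Ralgds, an activator of Ral GTPases, at 1.36 (SE 0.225, adjusted p = 0.326). The difference of Il12b was -3.44, -4.59 and -3.79 in the 3 experiments and that of Nfkbie 3.62, 2.63 and 3.53. Il6 and Il12b passed with the slide as a random block, which called 2 genes, and Edn1, Il6, Il12b and Cxcl11 with array weights, which called 4. In MyD88-null cells Il6 rose at least 4.43-fold, Il12b at least 3.16-fold, Edn1 at least 5.89-fold and Csf2 at least 3.1-fold, all from control levels not well above background, so the true difference is not fixed by these values.

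At the level of lists, NF-kappaB genes responded more in MyD88-null cells (median difference 0.56, 6 members higher adjusted over the list alone, adjusted p = 4.99e-10), as did interferon-stimulated genes (median 0.97, none adjusted over the list alone, adjusted p = 6.49e-09) and chemokines (median 1.13, 2 higher adjusted over the list alone, adjusted p = 0.00671). In MyD88-null controls, NF-kappaB genes and chemokines started from lower levels than in C57BL/6 controls (medians -1.44 and -1.4). With apoA-I they still lay lower (-0.455 and -1.48), so their larger rise did not reach a higher level. Cytokines responded less (median -0.47, 4 lower adjusted over the list alone, adjusted p = 2.9e-08), and so did cholesterol synthesis genes (median -0.23, none adjusted over the list alone, adjusted p = 0.00175). None of the 5 calls held with an estimated correlation: for NF-kappaB genes adjusted p = 0.0659 with an estimated correlation, for interferon-stimulated genes 0.152, for chemokines 0.174, for cytokines 0.0546 and for cholesterol synthesis 0.32. The chemokine call was also lost without MyD88-null control replicate 1 (adjusted p = 0.108) and without MyD88-null apoA-I replicate 2 (adjusted p = 0.28), and the cholesterol synthesis call without MyD88-null control replicate 3 (adjusted p = 0.436). In the 3 experiments the median difference was 1.11, 1.48 and -0.017 for interferon-stimulated genes and 1.6, 0.371 and 0.0574 for chemokines. Leaving out an array moved the NF-kappaB median to 0.22 (without MyD88-null apoA-I replicate 2) and the cytokine median to -0.29, -0.17, -0.25 and -0.28 (without C57BL/6 control replicate 3, C57BL/6 apoA-I replicate 2, MyD88-null control replicate 1 and MyD88-null apoA-I replicate 1). The chemokine median moved to 0.68, 0.61, 1.79 and 0.60 (without C57BL/6 control replicate 1, MyD88-null control replicate 2 and MyD88-null apoA-I replicates 1 and 2), and the cholesterol synthesis median to -0.10, -0.35 and -0.037 (without C57BL/6 apoA-I replicate 3 and MyD88-null control replicates 1 and 3) and to -0.13, -0.13 and -0.37 (without MyD88-null apoA-I replicates 1, 2 and 3). Inflammatory effectors had a median of 0.21 (adjusted p = 0.176), with 2 higher, Acod1 and Tlr2, and 1 lower, the clotting initiator F3, adjusted over the list alone.

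**Figure D3:**
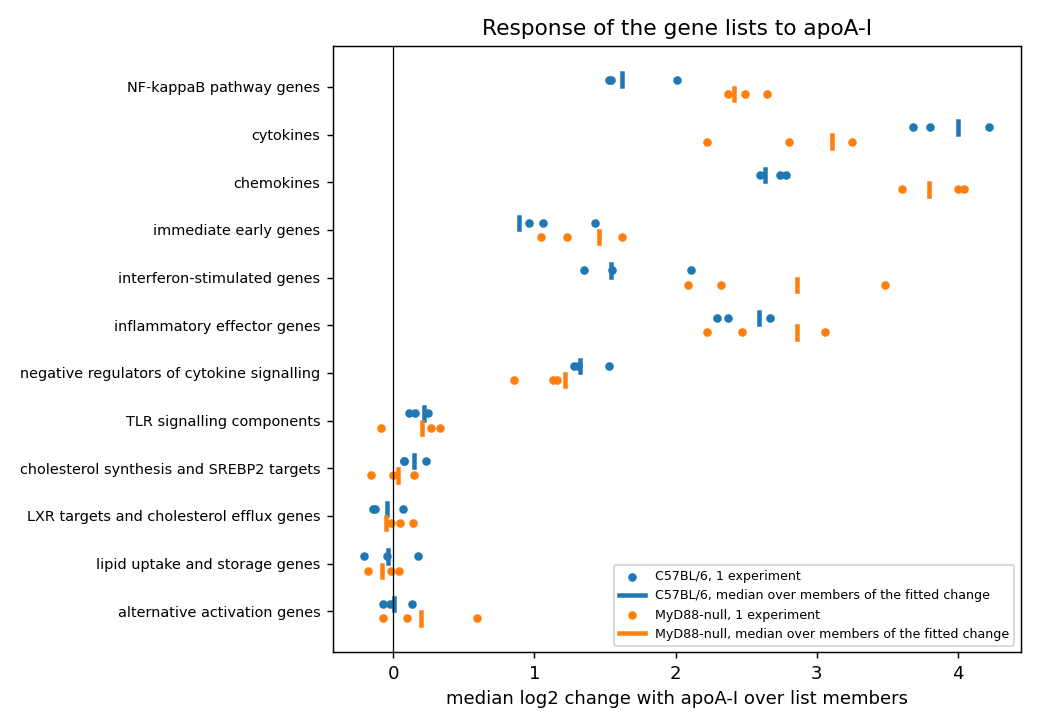
Median log2 change with apoA-I over the measured members of 12 gene lists; dots are single experiments and bars the median over members of the fitted change, in C57BL/6 cells (blue) and MyD88-null cells (orange). The 7 upper lists lie above 0 in every experiment of both genotypes, with cytokine medians of 4.0 and 3.11.

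The genotypes were next compared in control cells, which asks how MyD88-null macrophages differed before apoA-I. Inflammatory genes lay lower in MyD88-null cells. Cxcl1, a neutrophil attractant, was lower by a log2 difference of -5.57 (SE 0.704), 47.3-fold, with adjusted p = 0.0166 (n = 3 per group). Its MyD88-null controls were above background on 2 of 3 arrays. Il1b was at least 4.94-fold lower (adjusted p = 0.00302) and Csf3, the granulocyte growth factor, at least 4.9-fold lower (adjusted p = 0.00633), while Tnf was 17-fold lower (adjusted p = 0.0472) and Acod1 16-fold lower (adjusted p = 0.0163). In the other direction, Mela, a melanoma antigen gene of retroviral origin (chromosome 8, 122067110 to 122067169), was higher by 10.55 (SE 0.504, adjusted p = 1.82e-05), with C57BL/6 controls above background on 2 of 3 arrays.

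In all, 16 genes passed between control cells, 3 higher and 13 lower in MyD88-null cells, with 589 at an unadjusted p under 0.05. The other named decreases were Nfkbiz (11.6-fold), the nicotinic acid receptor Hcar2 (9.48-fold), Nfkbie (9.08-fold), Pde4b (4.91-fold) and Ralgds (3.79-fold, adjusted p = 0.002). Maff at -1.48, Lmo4 at -1.18 and Casp4 at -1.18 made up the rest of the 13, and A530053G22Rik, higher by 3.73 (adjusted p = 0.0166), was among the increases; these were chosen after their values were seen. Mela, Il1b, Csf3, Hcar2 and Ralgds kept their calls in all 12 fits with an array left out. Those of Tnf and Maff were lost in 11 of the 12, with adjusted p of up to 0.205 for each, and those of Cxcl1, Acod1, Nfkbie and Pde4b in 5 and of Nfkbiz in 4, with adjusted p of up to 0.122, 0.0883, 0.0796, 0.122 and 0.0628. The groups did not overlap for any of the 16 genes, which chance gives for 10% of genes and which held for 10.3% of all genes.

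Of 17 NF-kappaB pathway genes, 2 fell between control cells over all genes and 11 adjusted over the list alone (median -1.44, adjusted p = 2.61e-30). Of 21 inflammatory effectors, 1 fell and 14 adjusted over the list alone (median -1.31, adjusted p = 1.25e-25), of 16 chemokines 1 and 9 (median -1.40, adjusted p = 1.14e-19), and of 19 cytokines 3 and 6 (median -0.57, adjusted p = 1.97e-10). These 4 lists kept their calls with an estimated correlation (camera adjusted p = 0.00521, 0.00833, 0.00369 and 0.0313, in the order given). Lower medians that passed with the preset correlation only were -0.27 for cholesterol synthesis (adjusted p = 0.00067, and 0.284 with an estimated correlation), -0.26 for NRF2 genes (0.000342 and 0.206), -0.20 for unfolded protein genes (0.046 and 0.431), -0.13 for immediate early genes (0.0186 and 0.448, with Maff fallen), -0.33 for negative regulators (0.0258 and 0.243) and -0.35 for alternative activation genes (0.047 and 0.152). With the experiment as a block the last 3 were lost too, at adjusted p = 0.12, 0.0724 and 0.0529. Interferon-stimulated genes had a median of -0.21 (adjusted p = 0.077). Beside these groups, B cell markers lay lower in MyD88-null controls (median -0.43, adjusted p = 0.00415, and 0.284 with an estimated correlation), as did mast cell markers (median -0.65, adjusted p = 0.00783, and 0.152 with an estimated correlation), while macrophage markers had a median of -0.021 (adjusted p = 0.879). Leaving out MyD88-null control replicate 1 ended the calls of cholesterol synthesis (adjusted p = 0.132), NRF2 (0.0902), immediate early (0.126), alternative activation (0.509) and mast cell genes (0.107). Leaving out C57BL/6 control replicate 1 ended those of negative regulators (adjusted p = 0.141) and B cells (0.0603), and leaving out C57BL/6 control replicate 3 that of unfolded protein genes (0.55).

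Further calls between control cells were lost with single arrays. Those of unfolded protein genes were lost without C57BL/6 control replicate 2 (adjusted p = 0.0604), MyD88-null control replicates 1 and 2 (0.425 and 0.113) and MyD88-null apoA-I replicates 1 and 3 (0.0508 and 0.0722). Alternative activation genes lost theirs without C57BL/6 control replicate 3 (adjusted p = 0.501), C57BL/6 apoA-I replicates 1 and 2 (0.0519 and 0.0509), MyD88-null control replicate 2 (0.0635) and MyD88-null apoA-I replicates 2 and 3 (0.0518 and 0.0549). Negative regulators lost theirs without MyD88-null control replicates 1 and 2 (adjusted p = 0.0767 and 0.066). B cell markers lost theirs without C57BL/6 control replicate 2 (adjusted p = 0.0559) and MyD88-null control replicate 3 (0.051). Immediate early genes lost theirs without C57BL/6 control replicate 3 (adjusted p = 0.11), and cholesterol synthesis genes without MyD88-null control replicate 2 (0.0579). Medians moved too. Without C57BL/6 control replicate 1 they were -2.14 for chemokines, -0.049 for immediate early, -0.32 for unfolded protein and -0.25 for B cell genes. Without C57BL/6 control replicate 2 they were -0.20 for immediate early and -0.059 for B cell genes. Without C57BL/6 control replicate 3 they were -0.095 for unfolded protein, -0.42 for NRF2, -0.055 for alternative activation and -0.86 for B cell genes. Without MyD88-null control replicate 1 they were -0.87 for cytokines, -0.15 for cholesterol synthesis, -0.10 for unfolded protein and -0.14 for alternative activation genes. Without MyD88-null control replicate 2 they were -2.19 for inflammatory effectors and -0.42 for NRF2 genes. Without MyD88-null control replicate 3 that of B cell genes was -0.28.

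Between control cells 99 genes passed with the experiment as a block, 11 higher and 88 lower, all 16 among them. NF-kappaB medians were -1.6 within slide 1 and -1.6 and -1.15 within scan days 1 and 3. The count was 6, 8 and 6 without C57BL/6 control replicates 1, 2 and 3, 7 without MyD88-null control replicate 1 or 3, and 2, Mela and Il1b, without both samples whose descriptions conflict. With the treatment taken from those descriptions it was 2, Mela among them. With the slide as a fixed block Mela passed, as did the immunoglobulin-linked gene Jchain, lower in MyD88-null cells by -3.5 (limma's adjusted p = 0.0161).

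A targeted allele made in another strain can carry linked sequence, so differing genes were also located. Of the 15 differing genes with coordinates, 0 lay within 20 Mb of Myd88, against 270 of 16451 genes with coordinates (one-sided Fisher's exact p = 1), and with the experiment as a block 2 of 95 did (2.11%, one-sided Fisher's exact p = 0.464).

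In treated cells, the genotypes differed mainly in cytokines. With apoA-I, MyD88-null cells had lower levels of Il6, by a log2 difference of -5.33 (SE 0.416, adjusted p = 0.000759, n = 3 per group), Il12b by -4.52 (SE 0.347, adjusted p = 0.000759), Csf3 by -4.40 (SE 0.414, adjusted p = 0.00224), Il1a by -3.63 (SE 0.33, adjusted p = 0.00224) and Il1b by -3.32 (SE 0.326, adjusted p = 0.00281). Csf2 at -3.53, Edn1 at -3.50 and Nfkbiz at -3.14 were also lower. Mela was higher by 10.95 (SE 0.504) and Cxcl11, an interferon-induced chemokine, at least 2.31-fold (adjusted p = 0.0201). In all, 11 genes passed, 3 higher and 8 lower, with 656 at an unadjusted p under 0.05; the groups did not overlap for any of them, which chance gives for 10% of genes and which held for 5.62% of all genes.

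Of 19 cytokines, 6 fell between treated cells over all genes and 9 adjusted over the list alone (median -1.39, adjusted p = 5.39e-27). Of 16 chemokines, Cxcl11 rose over all genes, and 1 rose and 8 fell adjusted over the list alone (median -1.48, adjusted p = 1.89e-11), while of 21 inflammatory effectors 0 and 9 fell (median -0.90, adjusted p = 1.6e-21). These lists kept their calls with an estimated correlation, as did negative regulators (median -0.46, adjusted p = 1.28e-05), cholesterol synthesis genes (median -0.49, adjusted p = 9.66e-12) and hypoxia and glycolysis genes (median -0.23, adjusted p = 0.000285), none of which held a gene that passed over all genes. In the order given, camera's adjusted p with an estimated correlation was 0.00449, 0.00771, 0.0138, 0.0456, 0.0472 and 0.0217. NF-kappaB genes (median -0.46, adjusted p = 2.4e-09), NRF2 genes (median -0.40, adjusted p = 8.46e-09), interferon-stimulated genes (median 0.52, adjusted p = 3.26e-05), unfolded protein genes (median -0.30, adjusted p = 0.000169) and immediate early genes (median -0.15, adjusted p = 0.013) passed with the preset correlation only, with adjusted p = 0.0761, 0.0559, 0.284, 0.152 and 0.425 with an estimated correlation. Beside these, B cell markers (median -0.51, adjusted p = 0.000428) and mast cell markers (median -0.61, adjusted p = 0.00339) were lower, with adjusted p = 0.2 and 0.112 with an estimated correlation. The immediate early call was lost without C57BL/6 apoA-I replicate 1 (adjusted p = 0.462) and the interferon-stimulated call without MyD88-null apoA-I replicate 2 (adjusted p = 0.0637). Single arrays moved the NF-kappaB median to -0.29, -0.70 and -0.25 (without C57BL/6 apoA-I replicates 2 and 3 and MyD88-null apoA-I replicate 3), the unfolded protein median to -0.10 (without C57BL/6 apoA-I replicate 3) and the interferon-stimulated median to 0.80 (without MyD88-null apoA-I replicate 3). The immediate early median moved to -0.038 and -0.28 without C57BL/6 apoA-I replicates 1 and 3 and to -0.52, -0.044 and -0.052 without MyD88-null apoA-I replicates 1, 2 and 3, and the last pair also ended its call (adjusted p = 0.443 and 0.126).

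Between treated cells 38 genes passed with the experiment as a block, 7 higher and 31 lower, all 11 among them, and cytokine medians were -1.4 and -1.02 within slides 3 and 4. The count was 6 without both samples whose descriptions conflict, 2 with the treatment taken from those descriptions, 5 with the slide as a fixed block and 3 with a stricter filter on dim probes. Over all 5 comparisons, 49 of 130 list tests passed with the preset correlation, 22 with an estimated one and 44 with the experiment as a block. The median, mean and test of a list differed in sign in 17 tests of 11 lists, none of them past the threshold and with every test of the lipid uptake list among them.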

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

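The counts over other splits of the samples, apart from the swaps within experiments, and the test of a signal floor in control cells were written before their results were seen, and the other tests in this part were chosen only after the result was seen. A difference between genotypes in the response to apoA-I, by list test of the interaction, was seen for NF-kappaB genes (median 0.564), chemokines (1.13) and interferon-stimulated genes (0.971), which responded more in MyD88-null cells, and for cytokines (-0.474) and cholesterol synthesis genes (-0.231), which responded less. With an estimated correlation none of these calls held (adjusted p = 0.0659, 0.174, 0.152, 0.0546 and 0.32 with an estimated correlation, in the same order). The level with apoA-I was still lower in MyD88-null cells for NF-kappaB genes and chemokines (medians -0.455 and -1.48). Among 100 redrawings of the genotype labels, 43 gave at least the 5 lists seen, and the highest gave 14, so chance is not excluded for their number. With the pairs kept, by swapping genotypes within experiments and with the experiment as a block, 18 of 32 swaps gave at least 5 lists and the highest other gave 15, which does not exclude chance either. A swap in 1 treatment alone carries the genotype difference into the interaction. Among the 4 that swap whole experiments the highest other gave 2 lists, and 4 swaps cannot give a share under 0.05. For single genes the interaction called 0, a count that all 100 redrawings reach by construction, so they say nothing about chance there. Of these, 6 called any gene and the highest called 2939, a count that points to a structure of the samples, which was not identified.

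Ddx58, an RNA sensor, differed by 1.493 (C57BL/6 -0.1647, MyD88-null 1.329), Tlr9 by 1.039 (-0.2851 and 0.7543) and Xbp1, a transcription factor of the unfolded protein response, by -0.7462 (0.1226 and -0.6236). They were singled out among 190 named genes because every experiment of the genotypes moved in opposite directions. For Ddx58 this rests on the probe used: its other probes differed by 0.6355 and 0.1226, and the last had positive changes in both genotypes (0.02377 and 0.1464). By the limma test of the difference none of the 3 passed (adjusted p = 1 for each, unadjusted p = 0.0317, 0.43 and 0.101).

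For the counts within a genotype or treatment, 3 samples against 3 make 10 splits, which cannot give a share under 0.05. The real split alone reached its count, so that 1 of the 10 did so in each case: 139 genes against a highest other of 0 in C57BL/6 cells, 191 against 8 in MyD88-null cells, 16 against 0 between control cells and 11 against 0 between treated cells. With the experiment as a block, the real counts of 570, 682, 99 and 38 compare with 0 in the 3 other splits that part every pair.

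The first pattern is the lower level of NF-kappaB genes in MyD88-null control cells (median -1.44). Each SE in this paragraph comes from the spread over list members, not over samples. A difference between experiments is argued against by the medians within them, which were -1.6 (SE 0.3), -1.27 (SE 0.191) and -1.15 (SE 0.251), and one between slides or scan days, which the control arrays share in experiment 1 and in experiments 1 and 3, by the medians with slide (-1.393, adjusted p = 5.95e-17) or scan day (-1.348, adjusted p = 4.65e-18) as a fixed block. Fewer B cells or mast cells in the null cultures could lower these genes, but 7 B cell markers had a median of -0.428 (SE of the difference from the NF-kappaB genes 0.289) and 6 mast cell markers one of -0.651 (SE 0.292), smaller falls than that of the genes to be explained, as also with each control array left out in turn, where B cell medians ran from -0.857 (without C57BL/6 control replicate 3, NF-kappaB genes -1.54, SE 0.29) to -0.0592 (without C57BL/6 control replicate 2, NF-kappaB genes -1.35, SE 0.306). Jchain, an immunoglobulin-linked gene outside these markers, was lower by -3.5 with the slide as a fixed block, further than the NF-kappaB genes. A swapped label of replicate 2, where the descriptions conflict, leaves the NF-kappaB falls in experiments 1 and 3. Lower signalling without MyD88 may therefore account for the pattern, as a hypothesis found on these samples. Activation of the C57BL/6 cells before treatment and the unknown assignment of animals were not tested.

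The second pattern is the smaller cytokine response in MyD88-null cells (median difference -0.474). A signal floor in control cells may shorten the measured response where the null control level is not above background. Over the 12 cytokines above background on every array the median difference was -0.165 (SE over members 0.299), which leaves the floor open as an account of the response. Over 18 cytokines above background on every treated array the level with apoA-I was lower in MyD88-null cells by a median of -1.25 (SE over members 0.425), but a floor in control cells cannot reach that level, so the value does not bear on it. The interaction and the comparison of control cells use the same control arrays, so that their chance values are shared.

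The third pattern is the higher level of Mela in MyD88-null cells under both treatments. One candidate explanation is sequence linked to the targeted allele, which carries genes near Myd88 on chromosome 9. As an argument against sequence linked to the targeted allele, Mela lies on chromosome 8 in the array files. Among differing genes with coordinates, the number within 20 Mb of Myd88 was 0. A difference in strain background away from Myd88 was not tested.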

How the results depend on the processing

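Chosen only after the data were seen were the fits with scan day, without the 2 arrays of slide 2 and with 8 arrays for choosing genes, and the list tests with the slide as a block. The Myd88 difference stayed below 0 in every alternative run. Counts are given in the order C57BL/6 response, MyD88-null response, control genotype and treated genotype, and the median is that of the MyD88-null response of the genes higher in C57BL/6 cells. It lay above the C57BL/6 median in the fit reported (2.725 against 2.591) but below it with normexp background (C57BL/6 2.423), the replicate block (1.594), the slide as a fixed (2.413) or random block (1.526), array weights (1.527) and scan day (1.748), so its order is not settled. For the changes listed here the cause was not tested, except that fewer arrays were used where samples were left out.

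Normexp background gave 9 genes for control genotype, a median of 2.321 and a Myd88 difference of -1.311 (adjusted p = 0.0256). Without a filter the C57BL/6 count was 83 and the median 3.323. A stricter filter gave 3 for treated genotype and Myd88 at -1.334 (adjusted p = 0.0491). The replicate block, with the experiment as a block, gave 570, 682, 99 and 38, a median of 1.51 and Myd88 at -1.334 (adjusted p = 0.000939). It ended 5 list calls and gave 17 further calls of named genes in single comparisons, and changed no other call of a named gene or list. The slide as a fixed block gave 2 for control genotype, 5 for treated genotype and a median of 2.35. As a random block it gave 755, 659, 68 and 44, 2 for the interaction, a median of 1.351 and Myd88 at -1.25 (adjusted p = 0.0028). Trend and robust fitting gave 32 for control genotype and Myd88 at -1.334 (adjusted p = 0.0225). Array weights gave 760 and 382, 4 for the interaction, 82 for control genotype, a median of 1.419 and Myd88 at -1.3 (adjusted p = 0.0109). Scan day as a fixed block gave 323 and 357, 17 for treated genotype, a median of 1.706 and Myd88 at -1.286 (adjusted p = 0.00964).

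Without both samples whose descriptions conflict the counts were 59, 90, 2 and 6 and the median 3.293, and with the treatment from the description they were 0, 0, 2 and 2, with no median; these 2 were higher and 0 lower in each genotype comparison, instead of 3 and 13 in control and 3 and 8 in treated cells. Without the slide 2 arrays the MyD88-null count was 102. Fits with only the groups compared gave 81, 90, 1 (higher) and 5. An estimated correlation left 22 list tests past the threshold instead of 49. Choosing genes in 4 C57BL/6 arrays and reading the MyD88-null median in the held-out experiment, as planned, gave no genes and so no value. With 8 arrays for choosing, 30, 6 and 42 genes were chosen, and the held-out medians were 4.203, 4.284 and 3.009 in MyD88-null and 3.507, 8.16 and 3.13 in C57BL/6 cells in experiments 1, 2 and 3.

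Leaving out each array in turn gave 66 to 156 genes for C57BL/6, 115 to 186 for MyD88-null, 0 throughout for the interaction, 6 to 16 for control genotype and 8 to 13 for treated genotype. Medians ran from 2.534 to 3.372, list tests past the threshold from 40 to 52, and Myd88 from -1.472 to -1.236, past the threshold only without C57BL/6 apoA-I replicate 3 (adjusted p = 0.046). The C57BL/6 count was 69, 83, 92 and 66 without control replicates 2 and 3 and apoA-I replicates 1 and 2, the MyD88-null count 126 and 115 without control replicate 1 and apoA-I replicate 2, and the control genotype count 6, 8, 6, 7 and 7 without C57BL/6 control replicates 1, 2 and 3 and MyD88-null control replicates 1 and 3. Over all alternatives, 9360 values of named genes stayed on their side of the threshold or within their spread, 424 lost a call, 82 gained one and 288 moved; for lists these were 2114, 98, 59 and 199. Signal over background limits genes dim in control cells, such as Il6, Il12b and Csf2, whose folds are lower bounds or rest on few arrays.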

Other observations

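The test of a route without MyD88 in this part was chosen only after the result was seen. Among NRF2, metal and heat shock genes, the metallothionein Mt2 at 1.20 and the thioredoxin reductase Txnrd1 at 0.92 rose with apoA-I in C57BL/6 cells when adjusted over the list alone, and neither passed over all genes. Gbp5, an interferon-induced GTPase that passed in MyD88-null cells, had a change of 4.03 in C57BL/6 cells with adjusted p = 0.0607, or 0.0152 with the experiment as a block. Lpar6, which fell in MyD88-null cells, had a change of -1.28 in C57BL/6 cells (adjusted p = 0.25, or 0.028 with the experiment as a block). Over all arrays the first principal component held 49.4% of the variance and set experiment 3 apart, and the second held 15.5%. The arrays of experiment 3 were also the only ones scanned on day 3 and had the highest 75th percentiles. For these arrays alone, experiment, scan day and brightness cannot be told apart. Outside experiment 3 the first component also went with brightness. It was lowest, at -91, on the dimmest array, MyD88-null apoA-I replicate 1 (75th percentile 199.5). It was highest, at 31.4, on the brightest array outside experiment 3, MyD88-null control replicate 2 (591). The other arrays of experiment 2 lay at -55.4 to -27.8. The dimmest array and MyD88-null control replicate 2 were both scanned on day 2.

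One hypothesis is that part of the inflammatory response to apoA-I runs through a route that does not need MyD88. Interferon-stimulated genes are a known target of such routes downstream of Toll-like receptors 3 and 4, and their list rose in MyD88-null cells with adjusted p = 0.0145 with an estimated correlation. That value is the observation behind the hypothesis and does not test it. No receptor or adaptor was removed other than MyD88, so which route carried the response in MyD88-null cells stays untested. A microbial ligand in the apoA-I preparation might act through the same receptors. It was not tested, since no sample with such a ligand or with inactivated apoA-I was analysed here, and polymyxin B was present in all wells.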
